A study of Homo sapiens with 9 samples.

How the data were processed

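Total RNA from 9 samples of H9 cells was hybridised to Agilent 1-colour arrays labelled with Cy3. Per the file headers, the deposited intensities are processed signals of Agilent Feature Extraction, linear, background-subtracted and detrended within each array, with no normalization between arrays. The authors' series matrix, also without normalization between arrays, holds the same deposited intensities for probes with 1 spot: of 33128, 99.99% to 100% were equal to the scanner files within a relative 1e-05. Of 999 probes with several spots 85.1% to 89.9% were, with log2 differences of up to 5.41. Further steps by the authors are not stated. The other deposited columns used were the raw median and local background intensities and flags of 0 or 1 per spot.

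The processed signal was put on the log2 scale, spots of a probe were averaged without those marked as outliers, and each array's 75th percentile over non-control probes was subtracted. Probes were kept if well above background on all arrays of at least 1 group, which left 24971. Probes were named through their RefSeq accession and a gene table of assembly GRCh38.p14, used for names only: 25771 of 34127 had 1 symbol and 8356 none. Each symbol kept its brightest probe, giving 15620 genes, of which 3888 had more than 1 kept probe. Of 37 named genes with several probes, 2 (LAMA4, POU5F1) had a probe of opposite sign against NP and 8 had probes differing by over 1 on the log2 scale.

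Groups were compared with limma 3.58.1 in R 4.3.3 (a mean per group over all 9 arrays, 6 residual degrees of freedom, prior 2.31) and adjusted by Benjamini and Hochberg. Genes with an adjusted p under 0.05 were called. The 36 gene lists, fixed before the data were examined, were tested in 3 comparisons with camera (preset correlation 0.01), adjusted over all lists and comparisons, beside an estimated correlation and fry. camera compares a list with the other genes, and fry asks whether its genes move one way on balance. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. By a rule fixed at the same time, named genes were the 10 largest called differences in each direction without overlap between groups, up to 4 called members per list with up to 2 against its majority, and 21 genes whatever their values. A difference from a group not above background on any array is given as at least that over background.

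The labels number the differentiation sets, so arrays of 1 set were treated as pairs in an alternative with the set as a block. By residuals, sets pair D21 with D28 but not NP, though only set 3 does so across slides. Residuals of D21 and D28 arrays of 1 set correlated across genes at 0.301, 0.470 and 0.504, against -0.392 to 0.0862 for different sets, and those of NP with a sorted array of its set at -0.307 to -0.0044. Each slide was scanned once, so slide and scan cannot be told apart.

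On simulated data with the spread of these arrays (15620 genes, 5 simulations of 200 changed genes), 10.0%, 57.6%, 77.6% and 86.8% of genes changed 2-, 4-, 8- and 16-fold were recovered between D21 and NP, and 18.4%, 59.6%, 76.0% and 88.0% between D28 and NP. Between D28 and D21 81.2% and 88.4% of those changed 8- and 16-fold were, with 0 of the wrong sign. Unchanged groups sharing controls were simulated 100 times. The number of arrays limits the precision.

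Alternatives were normexp background correction (offset 50, on the median signal because the files lack the mean), quantile normalization, each array's median, the series matrix values, no or a stricter filter on dim probes, the mean of the probes, only the 2 groups compared, an intensity trend with robust spread, a block for set or slide, and each array left out. A block for the set with only the 2 groups compared was chosen after the data were seen. Control probes were left out, and probes without a symbol were tested apart.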

Results

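H9, an established line of human embryonic stem cells, was differentiated through neural progenitors toward astrocytes, to find genes that increase or decrease on the way. Total RNA was measured on 9 Agilent 1-colour arrays in 3 groups of 3. The first group, NP, holds unsorted neural progenitor cells of day 0. The others, D21 and D28, hold cells of days 21 and 28 sorted for CD44, a receptor for hyaluronan that the submitters used as a marker of astrocyte progenitors. Each group has 1 array from each of 3 differentiation sets, so replicates are separate differentiations of 1 line. Only the later groups were sorted, so day and sorting cannot be told apart in any comparison with NP.

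On each array 69.8% to 78.0% of 34127 probes were well above background. The 75th percentile of the processed signal ran from 477 (D28 replicate 1) to 1208 (D21 replicate 2), no spot was saturated, and 15620 named genes were tested. The first principal component held 48.0% of the variance and placed the NP arrays between -108 and -81.3 and the sorted arrays between 26.1 and 70.7. Genes are given below as log2 difference ± standard error over 3 arrays a group, with limma's adjusted p, and lists as the median log2 difference of the tested members. Lists were tested with camera at its preset correlation and with an estimated one, under which no list passed (smallest adjusted p = 0.194). A list's adjusted p is the former, and the one marked estimated the latter. Slides 1 and 2 held arrays of all groups, slide 3 only D28 replicate 3. Member counts marked list alone, given where they differ, are adjusted over that list's members only. Slide medians are, in order, with the slide as a block and within slides 1 and 2. Within these at least 1 side is 1 array. For a call lost without 1 array or with a block, the number after a name is the adjusted p there, the highest of several.

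In CD44-sorted cells of day 21, genes of the astrocyte lineage were higher than in the day 0 progenitors. GFAP, the intermediate filament of astrocytes, rose by 10.18 ± 0.84 (adjusted p = 0.00433), at least 245-fold. It was well above background on no NP array, and the rise was 10.47 within slide 1 and 9.97 within slide 2. Early glial and astrocyte progenitor genes rose as a list (median 1.70, adjusted p = 2.69e-07, or 0.194 estimated). Of 20 members 10 rose and 0 fell (list alone 12 and 1), slide medians 1.69, 1.65 and 2.16. The largest rises in the list were those of the integrin subunit ITGB4 (6.95 ± 0.81), tenascin C or TNC (4.83 ± 0.86), CD44 (4.65 ± 0.79) and NFIX (4.63 ± 0.54). CD44, the gene of the sort, rose by 3.31 within slide 1 and 6.38 within slide 2. NFIA (3.38 ± 0.49) and NFIB (2.59 ± 0.54), which promote the switch from neuron to glia formation, rose with SOX9 (1.97 ± 0.44), a transcription factor of glial fate. Adjusted p over these ran from 0.00433 to 0.0407. TNC (0.0808) lost the call without NP replicate 2 or 3. CD44 (0.0675) lost it without NP replicate 2 or 3 or D21 replicate 2 or 3. NFIB (0.121) lost it without NP replicate 2 or 3 or any D21 array. SOX9 (0.139) lost it without NP replicate 2 or 3, any D21 array or D28 replicate 1 or 2. NFIB (0.0790) lost it with the slide block, and NFIB (0.0729) with the set block.

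Astrocyte markers shifted up as a list (median 1.16, adjusted p = 0.000833, or 0.306 estimated). Of 25 members 3 rose and 1 fell (list alone 7 and 2), slide medians 1.14, 0.91 and 0.93. Besides GFAP the folate enzyme ALDH1L1 (5.08 ± 0.86) and the matrix protein SPARCL1 (4.98 ± 1.12) rose, and the growth factor receptor FGFR3 (-1.49 ± 0.36) fell (adjusted p from 0.0175 to 0.0474). SPARCL1 (0.119) and FGFR3 (0.146) lost the call without any NP array, D21 replicate 2 or 3 or D28 replicate 2. ALDH1L1 (0.0674) lost it without NP replicate 2 or 3. SPARCL1 (0.0660) and FGFR3 (0.0649) lost it with the slide block. The median moved over 1.5 times without D21 replicate 2 (astrocyte 0.56). S100B and 5 further genes fixed for naming did not pass. S100B had 3.90 ± 0.96 (adjusted p = 0.0516), and passed with the slide (0.0293) or the set (0.0172) as a block. The water channel AQP4 had 0.75 ± 1.63, the glutamate transporters SLC1A2 and SLC1A3 had 1.29 ± 1.06 and 1.09 ± 0.42, the connexin GJA1 0.17 ± 0.54 and vimentin, VIM, of the early glial list, 0.47 ± 0.30. Their adjusted p ran from 0.149 to 0.870.

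Genes of the progenitor state fell. Neural progenitor genes fell as a list (median -1.24, adjusted p = 1.95e-05, or 0.194 estimated). Of 25 members 0 rose and 4 fell (list alone 0 and 8), slide medians -1.03, -0.79 and -1.76. Among called members the transcription factors SOX3 (-6.74 ± 0.94), OTX1 (-4.18 ± 0.78) and NR2F1 (-2.89 ± 0.64) fell most. PAX6, a transcription factor of neural progenitors, had -3.56 ± 0.89 (adjusted p = 0.0539), and passed with the slide (0.0329) or the set (0.0229) as a block. SOX1 (-1.24 ± 0.79), SOX2 (-0.86 ± 0.63) and NES (-0.76 ± 0.34) did not pass, with adjusted p from 0.208 to 0.428. Pluripotency genes fell (median -0.58, 0.00610, or 0.209 estimated). Of 12 members 0 rose and 3 fell (list alone 0 and 4), slide medians -0.57, -0.84 and -1.23. These included LIN28A (-5.25 ± 0.76), an RNA-binding protein that blocks let-7 maturation, and SALL4 (-3.87 ± 0.29), while POU5F1 had 0.047 ± 0.35 (adjusted p = 0.947). Chromatin and RNA processing genes high in progenitors fell (median -0.83, 5.92e-06, or 0.306 estimated). Of 20 members 0 rose and 3 fell (list alone 0 and 6), slide medians -0.75, -0.54 and -0.76. The largest falls of called members were those of IGF2BP1 (-2.33 ± 0.38) and HMGA1 (-2.27 ± 0.31). Adjusted p over the genes that fell ran from 0.00345 to 0.0392. By over 1.5 times, medians moved without D21 replicate 3 (pluripotency -0.38) and D21 replicate 2 (chromatin -0.50). OTX1 (0.0857) lost the call without NP replicate 2 or 3 or D21 replicate 1 or 3. NR2F1 (0.126) lost it without NP replicate 2 or 3, any D21 array or D28 replicate 2. IGF2BP1 (0.0598) lost it without NP replicate 2 or 3.

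Neuronal genes had median -0.70 (adjusted p = 0.169), 1 of 27 up, 2 down. The list passed with the slide as a block (-0.94, adjusted p = 0.0137) and without D21 replicate 2 (-1.83, adjusted p = 0.00127). In it the proneural factors NEUROG1 (-5.24 ± 0.75) and NEUROG2 (-5.15 ± 0.67, at least 12.6-fold) fell and GAP43 (2.74 ± 0.56), a growth cone protein, rose. DCX (-1.62 ± 1.42), TUBB3 (0.10 ± 0.27) and MAP2 (-0.48 ± 0.63) did not pass, with adjusted p from 0.510 to 0.858. S phase and DNA replication genes fell as a list (median -0.90, 8.55e-05, or 0.516 estimated). Of 23 members 0 rose and 1 fell (list alone 0 and 0), slide medians -0.77, -0.44 and -1.06. Mitosis genes did too (median -1.29, 0.000110, or 0.542 estimated). Of 23 members 0 rose and 0 fell, slide medians -1.18, -0.51 and -1.47. The replication helicase subunit MCM2 (-1.56 ± 0.36) was the member called, and MKI67 had -1.08 ± 0.69 (adjusted p = 0.365). The largest falls among the named genes also took in PRDM12 (-7.47 ± 0.80), a factor of sensory neuron precursors, TESMIN (-7.21 ± 0.76, at least 37.1-fold), PRTG (-6.42 ± 0.74) and the natriuretic peptide gene NPPC (-5.83 ± 0.91, at least 30.5-fold). With them fell GRM3 (-5.54 ± 1.26), a metabotropic glutamate receptor, CRYGC (-5.36 ± 0.70, at least 17.4-fold) and TRIM71 (-5.35 ± 0.62). Adjusted p over these ran from 0.00681 to 0.0452. List medians moved over 1.5 times without D21 replicate 1 (S phase -1.36) and D21 replicate 2 (S phase -0.44, mitosis -0.70). GAP43 (0.111) lost the call without any NP array or any D21 array. MCM2 (0.149) lost it without any NP array, D21 replicate 2 or 3 or any D28 array. NPPC (0.0521) lost it without NP replicate 2 or 3. GRM3 (0.141) lost it without any NP array, D21 replicate 1 or 3 or D28 replicate 1 or 2. MCM2 (0.0977) lost it with the slide block, and GAP43 (0.0511) and MCM2 (0.0851) with the set block.

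Mesenchymal genes had the largest median of the 36 lists. Mesenchymal and fibroblast genes rose (median 3.17, adjusted p = 7.51e-15, or 0.234 estimated). Of 24 members 15 rose and 0 fell (list alone 22 and 0), slide medians 3.24, 2.90 and 3.59. Examples are periostin or POSTN (6.84 ± 1.16), the fibroblast surface protease FAP (5.57 ± 0.86) and the collagens COL6A3 (4.41 ± 0.59) and COL1A1 (4.24 ± 0.42). In no list, but among the 10 named genes that rose most, was OGN (8.46 ± 1.13, at least 142-fold). So were ASPN (7.69 ± 1.03, at least 55.1-fold), TNMD (7.67 ± 1.17), MFAP4 (6.72 ± 0.88) and FBLN5 (6.57 ± 0.96). The stress protein gene NUPR1 (7.21 ± 0.59) and the cytokine gene IL17B (6.57 ± 0.67, at least 24.4-fold) were there too. Adjusted p over these ran from 0.00433 to 0.0176. POSTN (0.0675) lost the call without NP replicate 3 or D21 replicate 2 or 3. FAP (0.0559) lost it without NP replicate 3 or D21 replicate 3.

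Smooth muscle and pericyte genes shifted up (median 1.67, adjusted p = 0.00115, or 0.446 estimated). Of 13 members 1 rose and 0 fell (list alone 2 and 0), slide medians 1.39, 1.08 and 2.26. The member called was smooth muscle actin, ACTA2 (4.45 ± 0.99). Extracellular matrix and basement membrane genes rose (median 1.05, 8.88e-05, or 0.287 estimated). Of 25 members 2 rose and 0 fell (list alone 11 and 1), slide medians 1.13, 0.52 and 1.69. The called members were LAMA4 (2.60 ± 0.55), of which another probe had the opposite sign, and TIMP1 (2.37 ± 0.43). Integrin and adhesion receptor genes rose (median 1.49, 2.96e-06, or 0.209 estimated). Of 19 members 5 rose and 0 fell (list alone 9 and 0), slide medians 1.40, 0.85 and 1.88. The collagen receptor subunits ITGA11 (4.14 ± 0.53) and ITGA1 (2.92 ± 0.56) led those called. BMP and TGF-beta response genes rose (median 1.25, 0.00339, or 0.360 estimated). Of 21 members 4 rose and 0 fell (list alone 8 and 0), slide medians 1.36, 1.13 and 1.54. Examples are TGFBI (4.23 ± 0.77) and TGFB2 (2.42 ± 0.53). Adjusted p over the genes named here ran from 0.00839 to 0.0394. By over 1.5 times, medians moved without D21 replicate 3 (smooth muscle 0.85, BMP and TGF-beta 0.46) and NP replicate 3 (BMP and TGF-beta 0.79). ACTA2 (0.112) lost the call without any NP array, D21 replicate 1 or 3 or D28 replicate 2. LAMA4 (0.125) lost it without NP replicate 2 or 3, D21 replicate 1 or 3 or D28 replicate 2. TIMP1 (0.0844) lost it without NP replicate 2 or 3 or any D21 array. ITGA1 (0.0945) lost it without NP replicate 1 or 3 or D21 replicate 1 or 3. TGFBI (0.0760) lost it without NP replicate 2 or D21 replicate 1 or 3. TGFB2 (0.115) lost it without any NP array, D21 replicate 1 or 3 or D28 replicate 1. ACTA2 (0.0581), LAMA4 (0.0648) and TGFB2 (0.0750) lost it with the slide block, and LAMA4 (0.0645), ITGA1 (0.0578) and TGFB2 (0.0748) with the set block.

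Lists of response genes rose as well. Immediate early and dissociation response genes rose (median 1.97, adjusted p = 1.67e-07, or 0.194 estimated). Of 18 members 6 rose and 0 fell (list alone 14 and 0), slide medians 2.02, 1.63 and 2.17. The transcription factors KLF2 (4.84 ± 1.05) and FOS (4.76 ± 0.53) led those called. Reactive astrocyte genes rose (median 1.20, 0.000241, or 0.194 estimated). Of 21 members 7 rose and 0 fell (list alone 11 and 1), slide medians 1.27, 1.5 and 1.1. Inducible prostaglandin synthase, PTGS2 (5.76 ± 0.97, at least 20.9-fold), and TM4SF1 (3.55 ± 0.66) rose most of the called members. Interferon response genes rose (median 1.28, 0.000708, or 0.413 estimated). Of 21 members 2 rose and 0 fell (list alone 5 and 0), slide medians 1.35, 1.94 and 0.64. IFI44 (3.01 ± 0.65) and B2M (1.98 ± 0.29) were called. JAK-STAT and gp130 pathway genes rose (median 1.11, 0.000241, or 0.194 estimated). Of 18 members 2 rose and 0 fell (list alone 5 and 0), slide medians 1.18, 1.41 and 0.97. The interleukin 6 receptor IL6R (3.63 ± 0.80) and the kinase JAK2 (1.35 ± 0.28) were called. Hypoxia response genes rose (median 1.71, 0.00104, or 0.287 estimated). Of 14 members 4 rose and 0 fell (list alone 7 and 0), slide medians 1.54, 0.83 and 1.89. Examples are VEGFA (3.45 ± 0.59) and NDRG1 (3.40 ± 0.61). Adjusted p over these ran from 0.00681 to 0.0384. Interferon response genes (0.0556) lost the list call without D21 replicate 1. The median moved over 1.5 times without NP replicate 1 (interferon 0.77) and D21 replicate 1 (interferon 0.70). PTGS2 (0.0671) and B2M (0.05005) lost the call without NP replicate 3. KLF2 (0.125) lost it without any NP array, any D21 array or D28 replicate 2. TM4SF1 (0.0747) lost it without NP replicate 1 or 3 or any D21 array. IFI44 (0.128) lost it without any NP array, D21 replicate 1 or 3 or D28 replicate 1 or 2. IL6R (0.133) lost it without NP replicate 1 or 3, any D21 array or D28 replicate 2. JAK2 (0.119) lost it without NP replicate 2 or 3 or any D21 array. VEGFA (0.0662) lost it without NP replicate 2 or 3 or D21 replicate 2 or 3. NDRG1 (0.0808) lost it without any NP array or D21 replicate 3. TM4SF1 (0.0526) and IL6R (0.0572) lost it with the set block.

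Cholesterol synthesis genes rose (median 1.13, adjusted p = 3.94e-06, or 0.413 estimated). Of 21 members 4 rose and 0 fell (list alone 9 and 0), slide medians 1.15, 0.45 and 1.53. INSIG1 (2.33 ± 0.38), a regulator of sterol synthesis, and the sterol enzyme CYP51A1 (1.30 ± 0.29) led those called. Heat shock and unfolded protein response genes rose (median 0.60, 0.00166, or 0.287 estimated). Of 21 members 1 rose and 0 fell, slide medians 0.73, 0.56 and 1.0. The member called was HERPUD1 (1.85 ± 0.31). Lysosome and autophagy genes rose (median 0.54, 0.0158, or 0.306 estimated). Of 20 members 2 rose and 0 fell, slide medians 0.57, 0.36 and 0.81. These were CD164 (1.5 ± 0.33) and LAMP2 (1.18 ± 0.23). Potassium channel and gap junction genes rose (median 0.94, 0.00272, or 0.194 estimated). Of 13 members 2 rose and 0 fell (list alone 4 and 0), slide medians 0.88, 1.15 and 2.12. These were the connexin GJB2 (6.19 ± 0.85) and the calcium-activated channel KCNMA1 (3.18 ± 0.51). HOX genes shifted up (median 1.49, 0.00307, or 0.514 estimated). Of 22 members 1 rose and 0 fell, slide medians 1.47, 0.77 and 1.71. The member called was HOXD1 (4.66 ± 0.98, at least 7.44-fold). Adjusted p over these ran from 0.00975 to 0.0395. Under the stricter filter on dim probes the HOX list did not pass (adjusted p = 0.0638). Lysosome genes (0.0501) lost the list call without NP replicate 3. HOX genes (0.156) lost it without NP replicate 1. List medians moved over 1.5 times without D21 replicate 2 (cholesterol 0.72, HOX 0.91), D21 replicate 1 (potassium channel 1.52), NP replicate 1 (HOX 0.61) and NP replicate 2 (HOX 2.73). INSIG1 (0.0647) lost the call without NP replicate 2 or 3. CYP51A1 (0.137) lost it without any NP array, D21 replicate 2 or 3 or D28 replicate 1 or 2. HERPUD1 (0.0693) lost it without NP replicate 2 or 3 or D21 replicate 3. CD164 (0.132) lost it without any NP array, any D21 array or D28 replicate 2. LAMP2 (0.103) lost it without NP replicate 2 or 3 or any D21 array. HOXD1 (0.119) lost it without any NP array or any D21 array. CYP51A1 (0.0690), CD164 (0.0778) and LAMP2 (0.0635) lost it with the slide block, and CYP51A1 (0.0701), CD164 (0.0653), LAMP2 (0.0634) and HOXD1 (0.0516) with the set block.

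Glutamate, GABA and amino acid handling genes shifted up weakly (median 0.65, adjusted p = 0.0476, or 0.514 estimated). Of 17 members 0 rose and 1 fell (list alone 1 and 1), slide medians 0.68, 0.18 and 0.94. Without a filter on dim probes this list had 0.20 and did not pass (adjusted p = 0.102), nor with the slide as a block (0.0913). Glutamate and GABA genes (0.334) lost the list call without NP replicate 1 or 3, D21 replicate 2 or D28 replicate 3. The median moved over 1.5 times without NP replicate 1 (1.03), D21 replicate 2 (0.42) and D21 replicate 3 (1.07). The lists of 6 other cell types did not pass. Oligodendrocyte lineage genes had median 0.44 (0.143), 2 of 11 up, 1 down (list alone 3 and 1). Neural crest and Schwann cell genes had median 0.50 (0.0825), 1 of 9 up, 0 down (list alone 2 and 1). Epithelial genes had median 0.037 (0.421), 1 of 10 up, 0 down. Endothelial genes had median -0.19 (0.665), 0 of 9 up, 1 down. Microglia and blood cell genes had median 0.34 (0.488), 1 of 7 up, 0 down. Choroid plexus and ependymal genes had median 1.01 (0.0612), 1 of 9 up, 1 down (list alone 4 and 1). Choroid plexus genes passed with the slide (1.1, adjusted p = 0.00857) or the set (0.0232, or 0.0155 with only the 2 groups) as a block, with only the 2 groups (0.0403) and with each array's median (0.0423). Neural crest genes passed by fry (0.0191). With 1 array left out, these passed: oligodendrocyte genes without NP replicate 3 (0.43); neural crest genes without NP replicate 2 (1.5) or NP replicate 3 (0.67); choroid plexus genes without NP replicate 2 (1.09), D21 replicate 3 (1.48) or D28 replicate 3 (1.01) (adjusted p from 0.0130 to 0.0493). Single members that rose include the keratin KRT14 (4.74 ± 0.53, at least 7.25-fold) and the macrophage receptor CSF1R (2.99 ± 0.36, at least 5.33-fold) (adjusted p from 0.00681 to 0.00745). KRT14 lost the call with normexp (0.110) and CSF1R with the series matrix values (0.0857).

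Of the pathway lists, Notch pathway genes had median 0.35 (adjusted p = 0.606), 1 of 13 up, 1 down (list alone 2 and 1). WNT pathway genes had median 0.015 (0.299), 1 of 19 up, 0 down (list alone 2 and 0). Glycolysis genes had median -0.056 (0.754), 0 of 17 up, 0 down. Lipid transport and storage genes had median 0.28 (0.0518), 2 of 13 up, 0 down (list alone 5 and 0). Cellular senescence and p53 target genes had median 0.68 (0.169), 2 of 15 up, 0 down. Cytokine and chemokine genes had median 0.75 (0.134), 0 of 16 up, 0 down. Lipid genes passed with the slide (0.50, adjusted p = 0.0296) or the set (0.0373, or 0.0208 with only the 2 groups) as a block and with only the 2 groups (0.0380). So they did with each array's median (0.0423), no filter on dim probes (0.0259), a stricter one (0.0455) or the mean of the probes (0.0484). Senescence genes passed by fry (0.0329). Leaving out 1 array, those that passed were cytokine genes without NP replicate 2 (0.81); lipid genes without D21 replicate 3 (0.58) or D28 replicate 1 or 2 (0.28) (adjusted p from 0.0106 to 0.0496). Among members called, NRARP (-2.05 ± 0.31), a feedback inhibitor of Notch signalling, fell, and IGFBP7 (3.59 ± 0.47) and FABP3 (3.27 ± 0.61) rose (adjusted p from 0.00856 to 0.0233). FABP3 (0.0656) lost the call without NP replicate 3 or any D21 array.

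In all, 618 genes were higher and 343 lower in D21 than in NP, 596 and 274 of them by at least 2-fold, with 3998 genes at an unadjusted p under 0.05 against 781 by chance. All 961 had the 3 arrays of 1 group above those of the other, as did 34.4% of all genes tested against 10% by chance. Within slides 1 and 2 their median sizes were 1.85 and 2.26 against 2.09 over all arrays. With the set as a block 481 were higher and 178 lower, and with the slide as a block 511 and 183. Higher and lower counts were smallest without NP replicate 3 (182 and 55), NP replicate 2 (216 and 58) and D21 replicate 3 (220 and 80). They were 294 and 151 without D21 replicate 2, 373 and 222 without D21 replicate 1, 389 and 198 without NP replicate 1 and 402 and 186 without D28 replicate 2. Of 96 called genes under the naming rule, 22 passed under every alternative that tested them and without each array: GFAP, OGN, ASPN, TNMD, NUPR1, ITGB4, IL17B, FBLN5, NFIX, NFIA, COL6A3, COL1A1, ITGA11, KCNMA1, PRDM12, TESMIN, SOX3, PRTG, TRIM71, NEUROG1, NEUROG2 and SALL4. Another probe differed by over 1 for GFAP (9.11), ASPN (5.79), NFIB (1.5), KCNMA1 (2.06) and TESMIN (-5.01).

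CD44-sorted cells of day 28, set against the same NP arrays, again had higher astrocyte genes. GFAP rose by 10.45 ± 0.84 (adjusted p = 0.00162), at least 296-fold, with 10.71 within slide 1 and 11.17 within slide 2. Early glial and astrocyte progenitor genes rose (median 1.64, adjusted p = 3.97e-06, or 0.194 estimated). Of 20 members 9 rose and 0 fell (list alone 12 and 1), slide medians 1.68, 1.28 and 2.00. ITGB4 (7.46 ± 0.81), CD44 (5.63 ± 0.79), NFIX (4.92 ± 0.54) and TNC (4.92 ± 0.86) led those called, and NFIA (2.95 ± 0.49), NFIB (2.25 ± 0.54) and SOX9 (1.87 ± 0.44) rose too. Adjusted p across these ran from 0.00162 to 0.0348. TNC (0.0524) lost the call without NP replicate 3. NFIB (0.114) lost it without NP replicate 2 or 3, D21 replicate 1 or D28 replicate 2 or 3. SOX9 (0.113) lost it without NP replicate 2 or 3 or D28 replicate 1 or 2. NFIB (0.112) lost it with the slide block, and NFIB (0.0708) with the set block.

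Astrocyte markers rose as a list at day 28 (median 1.09, adjusted p = 0.00270, or 0.355 estimated). Of 25 members 6 rose and 1 fell (list alone 8 and 2), slide medians 1.25, 0.75 and 1.84. SPARCL1 (4.57 ± 1.12), ALDH1L1 (4.03 ± 0.86) and the calcium-binding protein gene S100B (3.84 ± 0.96) rose, and FGFR3 (-2.40 ± 0.36) fell (adjusted p from 0.00818 to 0.0379). SPARCL1 (0.106) lost the call without any NP array, D21 replicate 3 or D28 replicate 2 or 3. ALDH1L1 (0.0835) lost it without any NP array or D28 replicate 1 or 2. S100B (0.122) lost it without NP replicate 2 or 3, D21 replicate 1 or D28 replicate 1 or 2. SPARCL1 (0.0725) lost it with the slide block. A list median moved over 1.5 times without D28 replicate 2 (astrocyte 0.61). AQP4 (1.38 ± 1.63), SLC1A2 (1.02 ± 1.06), SLC1A3 (1.39 ± 0.42), GJA1 (0.59 ± 0.54) and VIM (0.70 ± 0.30) did not pass, with adjusted p from 0.0648 to 0.609.

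Progenitor and neuronal genes fell by day 28. Neural progenitor genes fell (median -2.14, adjusted p = 2.96e-06, or 0.194 estimated). Of 25 members 0 rose and 12 fell (list alone 0 and 14), slide medians -1.48, -1.55 and -2.02. The falls included SOX3 (-6.60 ± 0.94), the Notch effector HES5 (-5.45 ± 1.1), LMO3 (-4.88 ± 1.09) and PAX6 (-4.66 ± 0.89). SOX1 (-1.93 ± 0.79), SOX2 (-1.09 ± 0.63) and NES (-0.80 ± 0.34) did not pass, with adjusted p from 0.144 to 0.283. Neuronal genes fell (median -1.38, 0.00624, or 0.514 estimated). Of 27 members 1 rose and 4 fell (list alone 1 and 7), slide medians -0.73, -1.0 and -1.06. Under the stricter filter the neuronal list did not pass (-0.43, adjusted p = 0.567). NEUROG1 (-7.18 ± 0.75, at least 47.9-fold), NEUROG2 (-5.50 ± 0.67, at least 10.2-fold) and NEUROD1 (-5.03 ± 1.16, at least 10.8-fold) fell and GAP43 (2.53 ± 0.56) rose. DCX had -3.70 ± 1.42 (adjusted p = 0.124) and passed with the slide as a block (0.0177). TUBB3 (-0.37 ± 0.27) and MAP2 (-1.08 ± 0.63) did not pass, with adjusted p from 0.283 to 0.401. Pluripotency genes fell (median -0.67, 0.00350, or 0.196 estimated). Of 12 members 0 rose and 4 fell, slide medians -0.58, -0.71 and -1.26. LIN28A (-5.85 ± 0.76, at least 22.9-fold) and LIN28B (-4.16 ± 0.79) led those called, and POU5F1 had -0.22 ± 0.35 (adjusted p = 0.702). The adjusted p of called genes ran from 0.00302 to 0.0307. By over 1.5 times, medians moved without D28 replicate 3 (neuronal -0.69) and NP replicate 2 (pluripotency -0.44). PAX6 (0.0620) and LIN28B (0.0669) lost the call without NP replicate 2 or 3 or D28 replicate 1. NEUROD1 (0.106) and GAP43 (0.0956) lost it without any NP array or D28 replicate 1 or 2. HES5 (0.0789) lost it without NP replicate 2 or 3. LMO3 (0.0955) lost it without NP replicate 2 or 3 or D28 replicate 1 or 3. HES5 (0.0775), NEUROD1 (0.0503) and LIN28B (0.0570) lost it with the slide block.

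Chromatin and RNA processing genes high in progenitors fell by day 28 (median -1.03, adjusted p = 8.16e-07, or 0.287 estimated). Of 20 members 0 rose and 9 fell (list alone 0 and 12), slide medians -1.25, -1.26 and -1.17. LIN28B, in this list too, the chromatin remodeller CHD7 (-2.60 ± 0.62) and IGF2BP1 (-2.44 ± 0.38) fell most. S phase and DNA replication genes fell (median -1.25, 2.96e-06, or 0.472 estimated). Of 23 members 0 rose and 3 fell (list alone 0 and 10), slide medians -1.31, -1.78 and -0.97. The helicase subunits MCM2 (-2.10 ± 0.36) and MCM7 (-2.01 ± 0.44) led those called. Mitosis genes fell as a list (median -1.26, 0.000564, or 0.582 estimated). Of 23 members 0 rose and 0 fell, slide medians -1.75, -2.44 and -1.07. MKI67 had -1.07 ± 0.69 (adjusted p = 0.332). The largest falls of named genes also included PRDM12 (-8.17 ± 0.80, at least 90.3-fold), TRIM71 (-7.35 ± 0.62, at least 83.6-fold), GRM3 (-7.25 ± 1.26), PRTG (-7.05 ± 0.74) and the neuronal splicing factor SRRM4 (-6.94 ± 1.33). SCRT2 (-6.70 ± 1.25), TESMIN (-6.61 ± 0.76, at least 30.1-fold) and TLX3 (-6.49 ± 1.31, at least 18.4-fold) completed them. The adjusted p of these ran from 0.00162 to 0.0330. A list median moved over 1.5 times without D28 replicate 1 (mitosis -0.73). CHD7 (0.109) lost the call without any NP array or D28 replicate 2. MCM7 (0.0888) lost it without any NP array or D28 replicate 1 or 2. Without NP replicate 2 or 3 SCRT2 (0.0623), SRRM4 (0.0678, also D28 replicate 1) and TLX3 (0.0714, also D28 replicate 1 or 2) lost it. GRM3 (0.0520) lost it without NP replicate 3. CHD7 (0.0625) and MCM7 (0.0553) lost it with the slide block, and MCM7 (0.0522) with the set block.

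Mesenchymal genes again had the largest median of the lists. Mesenchymal and fibroblast genes rose (median 3.14, adjusted p = 6.06e-14, or 0.256 estimated). Of 24 members 19 rose and 0 fell (list alone 20 and 0), slide medians 2.68, 2.36 and 2.86. They included POSTN (6.31 ± 1.16), FAP (6.24 ± 0.86), THBS2 (4.56 ± 0.72) and COL1A1 (4.06 ± 0.42). The 10 named genes that rose most held SLN (8.52 ± 0.90), NUPR1 (8.12 ± 0.59), OGN (7.67 ± 1.13, at least 82-fold) and APCDD1L (7.30 ± 0.56). Complement factor I, CFI (7.16 ± 0.77, at least 94.4-fold) but 3.31 by another probe, the metallothionein MT1M (7.11 ± 1.02, at least 73.4-fold), the transporter ABCC3 (6.91 ± 1.37) and ASPN (6.88 ± 1.03, at least 31.3-fold) were also among them. Adjusted p across these ran from 0.00161 to 0.0190. POSTN (0.0582) lost the call without NP replicate 3. ABCC3 (0.0623) lost it without any NP array or D28 replicate 1 or 2.

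Extracellular matrix and basement membrane genes rose (median 1.38, adjusted p = 0.000814, or 0.345 estimated). Of 25 members 5 rose and 1 fell (list alone 11 and 1), slide medians 0.98, 0.47 and 1.63. BGN (3.40 ± 0.83) and TIMP1 (3.24 ± 0.43) rose and the laminin chain LAMA1 (-2.21 ± 0.54) fell. Integrin and adhesion receptor genes rose (median 1.59, 1.34e-06, or 0.197 estimated). Of 19 members 8 rose and 0 fell (list alone 12 and 0), slide medians 1.68, 1.32 and 2.14. ITGA11 (3.48 ± 0.53) and ITGB3 (3.33 ± 0.58) led those called. BMP and TGF-beta response genes rose (median 0.91, 0.0217, or 0.462 estimated). Of 21 members 5 rose and 1 fell, slide medians 0.80, 0.45 and 1.1. TGFBI (4.65 ± 0.77) and TGFBR2 (2.31 ± 0.57) rose and ID2 (-1.58 ± 0.31) fell. Smooth muscle and pericyte genes shifted up (median 1.09, 0.0244, or 0.567 estimated). Of 13 members 0 rose and 0 fell, slide medians 0.62, -0.0068 and 1.33. That call ended with the slide as a block (adjusted p = 0.202). The adjusted p of these ran from 0.00535 to 0.0373. BMP and TGF-beta response genes (0.0534) lost the list call without NP replicate 3. Smooth muscle genes (0.192) lost it without NP replicate 3 or D28 replicate 3. A list median moved over 1.5 times without D28 replicate 1 (smooth muscle 1.76) and D28 replicate 3 (smooth muscle 0.56). BGN (0.106) lost the call without any NP array, D21 replicate 1 or any D28 array. LAMA1 (0.119) lost it without any NP array or D28 replicate 1 or 3. ITGB3 (0.0513) lost it without NP replicate 3. TGFBR2 (0.124) lost it without any NP array, D21 replicate 1 or D28 replicate 2 or 3. ID2 (0.0676) lost it without NP replicate 2 or D28 replicate 2. BGN (0.0898), LAMA1 (0.0851) and TGFBR2 (0.108) lost it with the slide block, and TGFBR2 (0.0619) with the set block.

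Response lists were higher at day 28 too. Interferon response genes rose (median 2.47, adjusted p = 2.69e-07, or 0.287 estimated). Of 21 members 10 rose and 0 fell (list alone 16 and 1), slide medians 2.63, 1.97 and 2.27. The interferon-induced genes IFIT2 (5.05 ± 1.01) and IFIT3 (4.84 ± 0.88) led those called. Immediate early and dissociation response genes rose (median 2.12, 6.51e-08, or 0.194 estimated). Of 18 members 10 rose and 0 fell (list alone 13 and 0), slide medians 2.22, 2.32 and 2.07. FOS (5.40 ± 0.53) and KLF2 (4.91 ± 1.05) led those called. Reactive astrocyte genes rose (median 1.29, 7.41e-05, or 0.194 estimated). Of 21 members 10 rose and 1 fell (list alone 12 and 2), slide medians 1.26, 1.05 and 1.87. The chemokine CXCL10 (6.84 ± 1.5) and PTGS2 (5.42 ± 0.97, at least 16.6-fold) rose most. JAK-STAT and gp130 pathway genes rose (median 1.36, 0.000195, or 0.194 estimated). Of 18 members 5 rose and 0 fell (list alone 7 and 1), slide medians 0.99, 1.04 and 1.38. The cytokine LIF (4.02 ± 1.08), of which another probe had 1.1, and IL6R (3.83 ± 0.80) rose. Cytokine and chemokine genes shifted up (median 0.89, 0.0221, or 0.423 estimated). Of 16 members 0 rose and 0 fell, slide medians 1.04, 2.46 and -0.11. Hypoxia response genes rose (median 1.63, 0.00139, or 0.287 estimated). Of 14 members 5 rose and 0 fell, slide medians 1.5, 1.82 and 1.25. VEGFA (3.51 ± 0.59) and NDRG1 (2.86 ± 0.61) led those called. Adjusted p across these ran from 0.00247 to 0.0475. Cytokine genes (0.151) lost the list call without NP replicate 1 or D28 replicate 1. A list median moved over 1.5 times without D28 replicate 2 (cytokine 1.44). IFIT3 (0.0516) and PTGS2 (0.0548) lost the call without NP replicate 3. IFIT2 (0.0588) lost it without D28 replicate 1. KLF2 (0.0852) lost it without NP replicate 2 or 3 or D28 replicate 2. CXCL10 (0.0770) lost it without NP replicate 3 or D28 replicate 1 or 2. LIF (0.139) lost it without any NP array, D21 replicate 2 or any D28 array. IL6R (0.0839) lost it without NP replicate 1 or 3 or D28 replicate 1 or 2. NDRG1 (0.0838) lost it without any NP array or D28 replicate 2. IFIT2 (0.0558), KLF2 (0.0570), CXCL10 (0.0596), LIF (0.0955) and NDRG1 (0.0682) lost it with the slide block, and CXCL10 (0.0546) and LIF (0.0789) with the set block.

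Heat shock and unfolded protein response genes rose (median 0.83, adjusted p = 0.000289, or 0.233 estimated). Of 21 members 5 rose and 0 fell (list alone 6 and 0), slide medians 0.73, 0.82 and 1.01. TRIB3 (2.32 ± 0.62) and DDIT3 (2.16 ± 0.45) led those called. Cholesterol synthesis genes rose (median 0.95, 9.96e-05, or 0.472 estimated). Of 21 members 4 rose and 0 fell (list alone 7 and 0), slide medians 1.17, 1.11 and 1.24. INSIG1 (2.13 ± 0.38) and the sterol enzyme MSMO1 (1.35 ± 0.36) led those called. Lysosome and autophagy genes rose (median 0.86, 0.000123, or 0.194 estimated). Of 20 members 6 rose and 0 fell (list alone 12 and 0), slide medians 0.86, 0.51 and 1.31. The autophagy receptor SQSTM1 (1.93 ± 0.49) and CD164 (1.80 ± 0.33) led those called. Cellular senescence and p53 target genes rose (median 1.32, 0.0182, or 0.194 estimated). Of 15 members 2 rose and 0 fell, slide medians 1.18, 0.79 and 1.30. IGFBP7 (3.92 ± 0.47) and the death receptor FAS (3.07 ± 0.41) were called. Potassium channel and gap junction genes rose (median 1.03, 0.00884, or 0.194 estimated). Of 13 members 2 rose and 0 fell, slide medians 1.67, 1.61 and 1.40. GJB2 (5.57 ± 0.85) and KCNMA1 (3.39 ± 0.51) were called, but the list did not pass under the stricter filter (adjusted p = 0.0579). Lipid transport and storage genes rose (median 0.92, 0.0414, or 0.355 estimated). Of 13 members 4 rose and 0 fell, slide medians 0.96, 0.58 and 1.34. FABP3 (3.06 ± 0.61) and APOL1 (1.83 ± 0.46) led those called, but the list did not pass with normexp (0.0729) or quantile normalization (0.0558). The adjusted p of these ran from 0.00438 to 0.0476. Lipid genes (0.0707) lost the list call without NP replicate 3 or D28 replicate 1 or 2. List medians moved over 1.5 times without NP replicate 2 (senescence 0.77, lipid 0.50), D28 replicate 1 (senescence 0.83, lipid 0.56), D28 replicate 3 (potassium channel 1.58) and D28 replicate 2 (lipid 0.51). TRIB3 (0.132) lost the call without any NP array, D21 replicate 3 or D28 replicate 1 or 2. DDIT3 (0.0822) lost it without NP replicate 2 or 3 or D28 replicate 1 or 2. INSIG1 (0.0573) lost it without NP replicate 2 or 3. MSMO1 (0.152) lost it without any NP array, D21 replicate 2 or 3 or D28 replicate 1 or 2. SQSTM1 (0.132) lost it without any NP array, D21 replicate 1 or 3 or D28 replicate 1 or 2. CD164 (0.0596) lost it without NP replicate 3. FABP3 (0.0560) lost it without NP replicate 3 or D28 replicate 1. APOL1 (0.122) lost it without any NP array, D21 replicate 3 or any D28 array. TRIB3 (0.0623), MSMO1 (0.0734), CD164 (0.0594) and APOL1 (0.0624) lost it with the slide block, and TRIB3 (0.0777) and MSMO1 (0.0822) with the set block.

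Other lists did not pass at day 28. Oligodendrocyte lineage genes had median 0.37 (adjusted p = 0.379), 1 of 11 up, 1 down (list alone 2 and 1). Neural crest and Schwann cell genes had median 1.02 (0.170), 1 of 9 up, 0 down (list alone 1 and 1). Epithelial genes had median 0.10 (0.299), 2 of 10 up, 0 down (list alone 2 and 1). Endothelial genes had median -0.052 (0.752), 1 of 9 up, 0 down. Microglia and blood cell genes had median 0.076 (0.499), 1 of 7 up, 0 down (list alone 1 and 1). Choroid plexus and ependymal genes had median 0.92 (0.242), 0 of 9 up, 1 down (list alone 2 and 1). Choroid plexus genes passed with the slide as a block (1.41, adjusted p = 0.0454) and neural crest genes by fry (0.0348). Called members included KRT14 (5.57 ± 0.53, at least 12.9-fold) and CSF1R (3.74 ± 0.36, at least 8.95-fold) (adjusted p from 0.00231 to 0.00238).

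Notch pathway genes had median -0.10 (adjusted p = 0.591), 0 of 13 up, 2 down (list alone 1 and 2). WNT pathway genes had median -0.15 (0.606), 3 of 19 up, 1 down (list alone 4 and 1). Glycolysis genes had median -0.028 (0.972), 0 of 17 up, 1 down. Glutamate, GABA and amino acid handling genes had median 0.41 (0.161), 1 of 17 up, 1 down. HOX genes had median 0.77 (0.151), 1 of 22 up, 0 down. Higher values passed for HOX genes without NP replicate 2 (2.07) (adjusted p = 0.000704). Among Notch genes NRARP (-3.25 ± 0.31) fell (adjusted p = 0.00231). For WNT, endothelial and glycolysis genes the median, mean and camera's direction differed in sign at day 28.

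Altogether 1036 genes were higher and 854 lower in D28 than in NP, 958 and 646 of them by at least 2-fold, with 4710 genes at an unadjusted p under 0.05 against 781 by chance. Arrays of the groups did not overlap for 38.8% of the genes tested, against 10% by chance, and for all 1890 called. Within slides 1 and 2 their median sizes were 1.73 and 1.82 against 1.80 over all arrays. The set as a block gave 891 higher and 568 lower, and the slide as a block 682 and 393. Without 1 array the counts were 387 and 156 (NP replicate 3), 453 and 181 (NP replicate 2), 528 and 319 (D28 replicate 2) and 672 and 334 (D28 replicate 1), and 547 were lower without NP replicate 1. Of 123 called genes under the naming rule, 18 passed under every alternative that tested them and without each array: GFAP, NUPR1, ITGB4, APCDD1L, CFI, KRT14, CSF1R, IFI44, FOS, IGFBP7, PRDM12, TRIM71, NEUROG1, PRTG, TESMIN, NEUROG2, SALL4 and NRARP. Another probe differed by over 1 for GFAP (9.12), ASPN (4.68), NFIB (1.16), KCNMA1 (1.5) and TESMIN (-5.39).

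**Figure D1:**
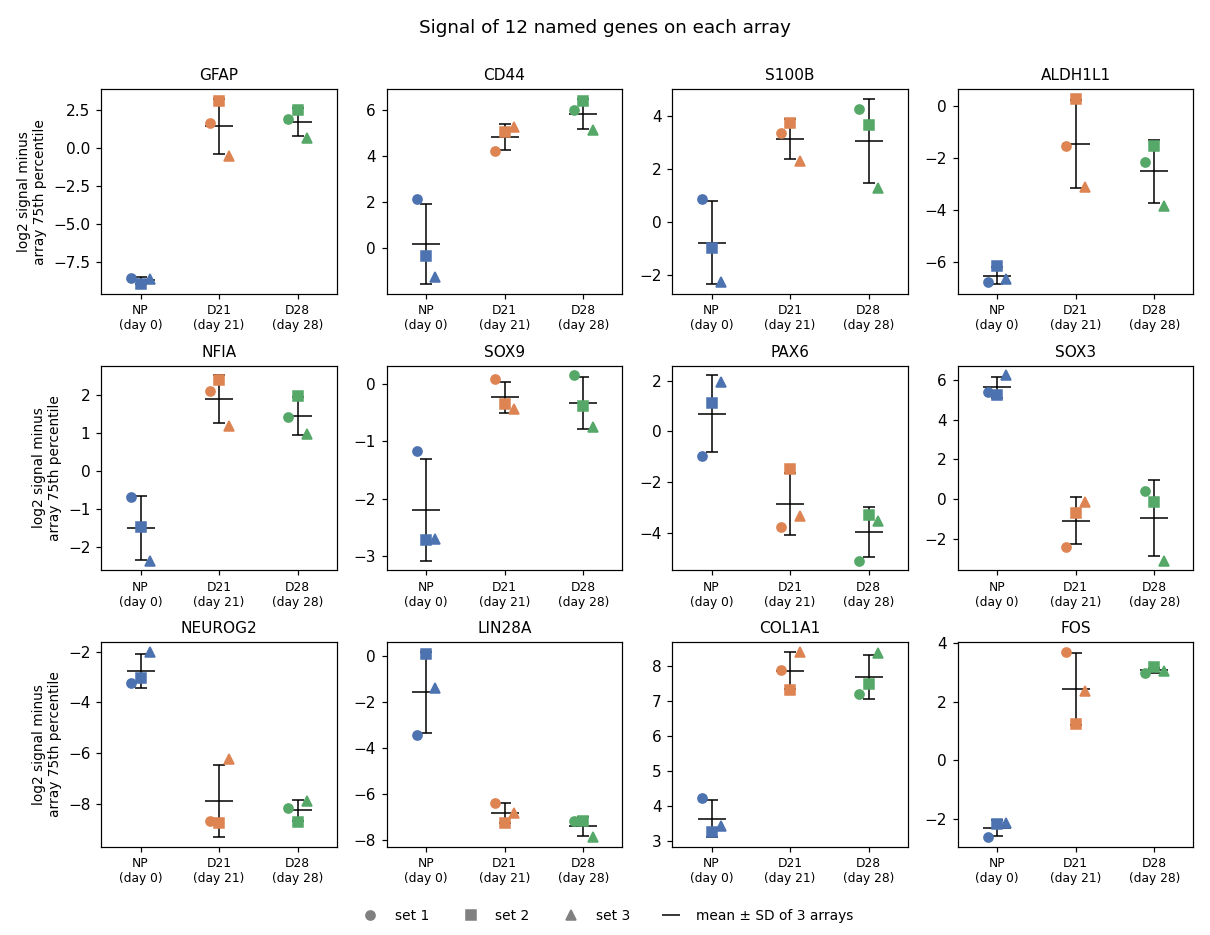
Log2 signal relative to each array's 75th percentile for 12 named genes, with 1 point per array, the marker shape giving the differentiation set, and mean ± SD of 3 arrays in black. GFAP had a mean of -8.73 ± 0.23 in NP, 1.45 ± 1.82 in D21 and 1.72 ± 0.94 in D28, and SOX3 lay between 5.27 and 6.26 on the NP arrays and between -3.12 and 0.40 on the sorted arrays.

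**Figure D2:**
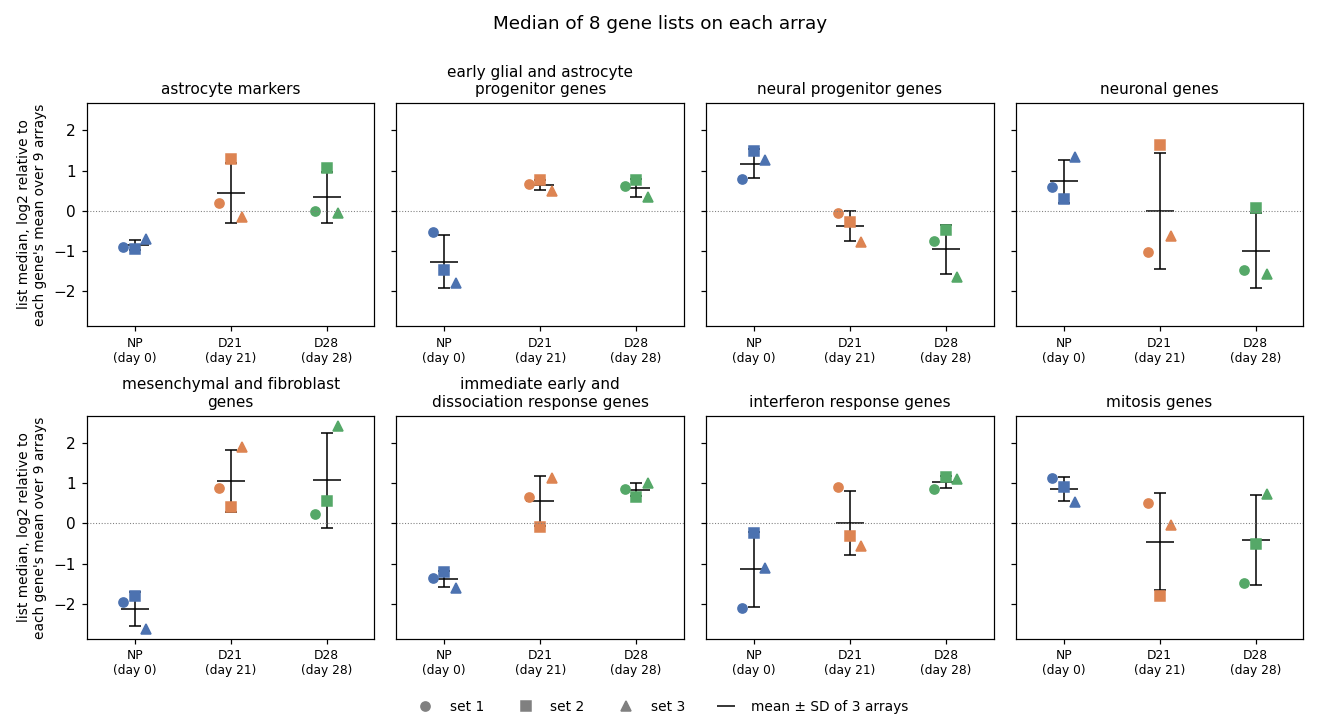
Median of 8 gene lists on each array, as log2 relative to each gene's mean over all 9 arrays (dotted line at 0), drawn in the same way. The mesenchymal list lay between -2.62 and -1.80 on the NP arrays and between 0.23 and 2.43 on the sorted arrays, and the interferon list between -0.56 and 0.92 in D21 and between 0.87 and 1.15 in D28.

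Most genes called at D21 were called at D28 as well, 885 of 961 and of 1890. Of these, 570 were higher and 315 lower than NP on both days, among them GFAP, OGN, ITGB4, NFIA and COL1A1 on the higher side and PRDM12, SOX3, NEUROG1, LIN28A and SALL4 on the lower, and 0 were called in opposite directions. Another 76 were called at D21 alone and 1005 at D28 alone, which is no test of a difference between the days. Both comparisons use the same NP arrays. Independent lists of these sizes would share 59.7, against 885 observed. Simulated unchanged groups have little to call (mean 0.01 shared, at most 1) and cannot gauge overlap where NP differs. Across genes, which are not independent replicates, the log2 differences correlated at 0.927, with covariance 1.21 (simulation 0.501 and 0.145). NP's 3 arrays could not be split into parts of at least 2, so part of the excess may come from shared controls or sets. The shared count was 569 with the slide as a block, and without 1 array it was lowest at 226 (NP replicate 3), then 259 (NP replicate 2), 296 (D21 replicate 3), 424 (D21 replicate 2), 478 (D28 replicate 2), 544 (D21 replicate 1) and 561 (NP replicate 1).

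**Figure D3:**
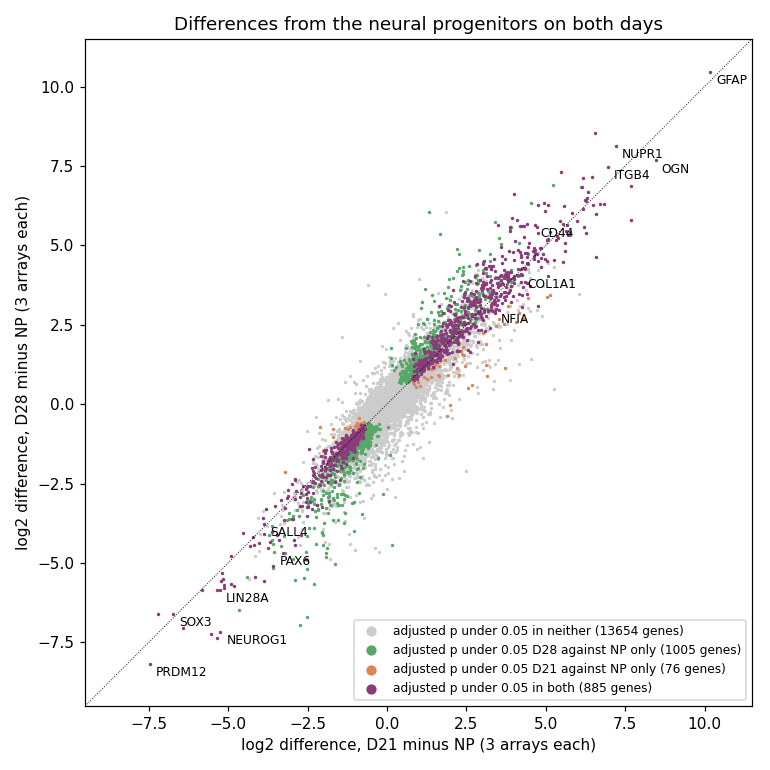
Log2 difference of each of the 15620 genes tested, D21 minus NP on the horizontal axis and D28 minus NP on the vertical axis, with the dotted line marking equal differences and colours giving where the adjusted p was under 0.05. The 885 genes called in both comparisons lie in the upper right and lower left, and GFAP lies at 10.18 and 10.45.

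Between the sorted groups, day 28 against day 21, no single gene passed limma's test. With 0 genes higher and 0 lower (smallest adjusted p = 0.9998), 313 had an unadjusted p under 0.05 against 781 by chance. CD44 had 0.98 ± 0.79, GFAP 0.27 ± 0.84, S100B -0.060 ± 0.96, ALDH1L1 -1.05 ± 0.86, NFIA -0.44 ± 0.49 and SOX9 -0.092 ± 0.44. PAX6 had -1.1 ± 0.89, DCX -2.08 ± 1.42, SOX2 -0.23 ± 0.63, MAP2 -0.60 ± 0.63 and MKI67 0.0016 ± 0.69. The other genes fixed for naming were AQP4 (0.62 ± 1.63), SLC1A2 (-0.27 ± 1.06), SLC1A3 (0.30 ± 0.42), GJA1 (0.42 ± 0.54), VIM (0.23 ± 0.30) and NFIB (-0.34 ± 0.54). SOX1 had -0.69 ± 0.79, NES -0.039 ± 0.34, TUBB3 -0.46 ± 0.27 and POU5F1 -0.27 ± 0.35. A missed threshold does not show that the days are alike. Residuals of D21 and D28 arrays of 1 set correlated, which neither the unpaired test nor the simulation uses. In simulated arrays with this spread, 14.0% of genes changed 2-fold and 61.2% of those changed 4-fold were recovered between these groups. With the set as a block and only the sorted arrays, a fit chosen after the data were seen, 0 genes passed limma's test and 717 had an unadjusted p under 0.05. Under the planned settings and with single arrays left out, 0 genes passed and 217 to 603 had an unadjusted p under 0.05.

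Some gene lists were higher in D28 than in D21 by camera, with 0 members called, and 0 adjusted over the list alone. Other splits of the sorted arrays called 6 to 11 lists, against 15. Interferon response genes had median 0.95 (adjusted p = 1.37e-11, or 0.194 estimated), slide medians 1.01, 0.067 and 1.39. Lysosome and autophagy genes had median 0.31 (8.16e-07, or 0.194 estimated), slide medians 0.36, 0.20 and 0.34. Cellular senescence and p53 target genes had median 0.49 (0.00419, or 0.194 estimated), slide medians 0.33, 0.44 and 0.33. Reactive astrocyte genes had median 0.24 (0.00771, or 0.287 estimated), slide medians 0.15, 0.19 and 0.11. Immediate early and dissociation response genes had median 0.31 (0.00884, or 0.378 estimated), slide medians 0.23, 0.13 and 0.27. Cytokine and chemokine genes had median 0.44 (0.0267, or 0.441 estimated), slide medians 0.62, 1.47 and -0.16. Integrin and adhesion receptor genes had median 0.35 (0.0437, or 0.514 estimated), slide medians 0.50, 0.59 and 0.21. Endothelial genes had median 0.15 (0.0218, or 0.233 estimated), slide medians 0.37, 0.52 and 0.98. Heat shock and unfolded protein response genes had median 0.12 (0.0345, or 0.413 estimated), slide medians 0.021, 0.23 and -0.057. Interferon and lysosome genes kept the call with the slide or the set as a block and without any 1 array. By fry their adjusted p was 0.158 and 0.0483. The interferon median within sets 1 (also slide 1), 2 and 3 was 0.067, 1.32 and 1.39. With the slide as a block the calls ended for heat shock (0.281), endothelial (0.0501) and immediate early genes (0.0582). Reactive astrocyte genes (0.407) and immediate early genes (0.975) lost the list call without D21 replicate 2 or D28 replicate 1. Senescence genes (0.135) lost it without D21 replicate 1, cytokine genes (0.929) without D21 replicate 1 or 2 or D28 replicate 1. Integrin genes (0.918) lost it without D21 replicate 1 or 2 or D28 replicate 2 or 3. Endothelial genes (0.148) lost it without D21 replicate 1 or 3 or D28 replicate 2 or 3. Heat shock genes (0.283) lost it without D21 replicate 1 or 2 or D28 replicate 1 or 3. Integrin genes also lost it with normexp (0.149), quantile normalization (0.0604), each array's median (0.0801) and no (0.101) or a stricter filter on dim probes (0.0867). Heat shock genes lost it with normexp (0.155), quantile normalization (0.0538), each array's median (0.0546) and no filter (0.0900), endothelial genes with no (0.0818) or the stricter filter (0.360) and cytokine genes with each array's median (0.0549). By over 1.5 times, medians moved without D28 replicate 1 (senescence 0.32, cytokine -0.11, endothelial 0.27), D28 replicate 3 (senescence 0.31, reactive 0.057, cytokine 0.67, endothelial 0.33, heat shock 0.072), D21 replicate 2 (reactive 0.10, immediate early -0.086, cytokine 0.19, endothelial 0.46), D21 replicate 3 (immediate early 0.58, heat shock 0.21), D21 replicate 1 (cytokine 0.68, integrin -0.046, endothelial 0.70) and D28 replicate 2 (cytokine 0.99, integrin 0.19, endothelial 0.29, heat shock 0.24).

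Neuronal, progenitor, Notch, HOX and S phase lists were lower in D28 than in D21, again with 0 members called and 0 adjusted over the list alone. Neuronal genes had median -0.58 (adjusted p = 2.25e-05, or 0.355 estimated), slide medians -0.65, 0.0089 and -0.75. Notch pathway genes had median -0.37 (0.000814, or 0.194 estimated), slide medians -0.13, -0.46 and -0.12. Neural progenitor genes had median -0.34 (0.00640, or 0.306 estimated), slide medians -0.27, -0.61 and 0.12. HOX genes had median -0.79 (0.00385, or 0.516 estimated), slide medians -1.22, -1.28 and -0.84. S phase and DNA replication genes had median -0.28 (0.00163, or 0.590 estimated), slide medians -0.65, -1.47 and 0.12. Chromatin and RNA processing genes high in progenitors had median -0.20 (0.0126, or 0.514 estimated), slide medians -0.40, -0.58 and -0.20. With the slide as a block the calls ended for neuronal (0.0504), Notch (0.0750) and neural progenitor genes (0.498). Neuronal genes (0.452) lost the list call without D21 replicate 2 or D28 replicate 3. Notch genes (0.104) lost it without D28 replicate 3. Neural progenitor genes (0.434) lost it without D21 replicate 1 or 2 or D28 replicate 3. HOX genes (0.411) lost it without D21 replicate 2 or D28 replicate 1. S phase genes (0.752) lost it without D21 replicate 1 or 3 or D28 replicate 1. Chromatin genes (0.551) lost it without D21 replicate 1 or 3 or D28 replicate 1 or 2. List medians moved over 1.5 times without D21 replicate 1 (neuronal -1.16, progenitor -0.15, HOX -0.52, S phase 0.085, chromatin -0.078), D21 replicate 2 (neuronal -0.089, HOX -0.47, S phase -0.90, chromatin -0.53), D21 replicate 3 (neuronal -1.19, Notch -0.60, progenitor -0.58, HOX -1.46, S phase -0.11, chromatin -0.028), D28 replicate 2 (neuronal -0.94, progenitor -0.90, chromatin -0.12), D28 replicate 3 (neuronal -0.88, Notch -0.12, S phase -0.54, chromatin -0.38) and D28 replicate 1 (Notch -0.63, progenitor -0.55, HOX -0.46, S phase -0.12).

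The remaining lists did not pass between the sorted groups, here with the median and camera's adjusted p. For the astrocyte lineage they were astrocyte markers (-0.028, 0.759) and early glial and astrocyte progenitor genes (-0.057, 0.993). For other cell types they were oligodendrocyte lineage genes (-0.12, 0.149), mesenchymal and fibroblast genes (-0.18, 0.422), smooth muscle and pericyte genes (-0.43, 0.0504) and neural crest and Schwann cell genes (-0.045, 0.515). With them were epithelial genes (0.095, 0.256), microglia and blood cell genes (0.073, 0.550), choroid plexus and ependymal genes (-0.37, 0.0880) and pluripotency genes (-0.31, 0.191). The pathway lists were mitosis genes (0.024, 0.759), extracellular matrix and basement membrane genes (-0.010, 0.688), BMP and TGF-beta response genes (-0.075, 0.300), JAK-STAT and gp130 pathway genes (0.16, 0.169) and hypoxia response genes (0.055, 0.905). Also among these were glycolysis genes (0.031, 0.543), cholesterol synthesis genes (-0.084, 0.185), lipid transport and storage genes (0.13, 0.483), glutamate, GABA and amino acid handling genes (-0.18, 0.242), potassium channel and gap junction genes (-0.033, 0.575) and WNT pathway genes (-0.13, 0.299). For the mesenchymal and early glial lists the median, mean and camera's direction differed in sign. With the slide as a block D28 rests on replicates 1 and 2. Lower values passed there for mesenchymal (-0.73, 0.00156) and smooth muscle genes (-1.01, 0.00120). Mitosis (-0.62, 0.00113) and oligodendrocyte lineage genes (-0.28, 0.0442) passed there too. Smooth muscle genes also passed with normexp (0.0126), quantile normalization (0.0385), each array's median (0.0219) and the series matrix values (0.0499). So they did with the stricter filter (0.0244), only the 2 groups (0.0206) and, with these, the set as a block (0.00571), in 8 of 14 alternatives. The set as a block with only the 2 groups, which pairs D21 with D28, added choroid plexus (0.0138) and glutamate and GABA genes (0.0376). Cholesterol (0.00878) and microglia genes (0.0222) passed with normexp, choroid plexus genes with each array's median (0.0486) and pluripotency genes with only the 2 groups (0.0426). With 1 array left out, passes were seen for astrocyte genes without D21 replicate 3 (-0.48); oligodendrocyte genes without D28 replicate 3 (-0.45); mesenchymal genes without D21 replicate 3 (0.23), D28 replicate 1 (0.42) or D28 replicate 3 (-0.77); smooth muscle genes without NP replicate 2 or 3 (-0.43), D21 replicate 2 (-0.85) or D28 replicate 3 (-1.1) (adjusted p from 0.000530 to 0.0334). They were also seen for choroid plexus genes without D21 replicate 3 (-0.82) or D28 replicate 2 (-0.41); mitosis genes without D21 replicate 1 (0.50), D21 replicate 2 (-0.67), D28 replicate 1 (0.54) or D28 replicate 3 (-0.55); BMP and TGF-beta genes without D21 replicate 2 (-0.33) (adjusted p from 1.2e-05 to 0.0325). Metabolic lists that passed so were cholesterol genes without D21 replicate 1 (-0.31), D28 replicate 1 (-0.26) or D28 replicate 2 (-0.11); glutamate and GABA genes without D21 replicate 1 (-0.37), D21 replicate 3 (-0.31) or D28 replicate 2 (-0.42) (adjusted p from 0.00124 to 0.0478). The number of members called was 0 in each list, and 1 oligodendrocyte lineage gene was lower adjusted over the list alone.

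Genes that moved the same way at both steps, NP to D21 and D21 to D28, were counted. As limma called none between D28 and D21, 0 genes moved in the same and 0 in opposite directions, as in simulated unchanged groups. D21 enters both steps with opposite sign. Across genes, which are not independent replicates, the differences of both steps correlated at 0.0917, with covariance 0.045 (simulation -0.499 and -0.144). The simulation lacks sets, whose D21 and D28 arrays deviate together, so the gap decides nothing.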

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

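The tests of the 3 patterns below were chosen after the results were seen, and the splits of the arrays before.

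Mesenchymal and fibroblast genes had a median of 3.17 in D21 and 3.14 in D28 against NP, and all 24 tested members, COL1A1 included, were higher in both sorted groups. With quantile normalization or each array's median, the lower of the D21 medians was 3.13. Over all genes these scalings moved the D21 differences by medians of only -0.02 and -0.0405. The choice among the scalings thus does not account for the pattern, but errors that they share were not tested. Cells of a mesenchymal type among those sorted cannot be told apart from a change within the astrocyte lineage, since the count of 24 higher members restates the pattern and decides nothing. COL1A1 had a mean of 3.63 in NP, 7.88 in D21 and 7.69 in D28, and a sort for CD44 would not remove cells that carry CD44. All 24 were above background on all NP arrays too, and 0 belong to another list. Sorting and time in differentiation cannot be told apart, as the series holds no unsorted later arrays, and the sorted groups differed by -0.18.

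Interferon response genes were higher in D28 than in D21 (median 0.95, 21 members, 20 above background on all NP arrays). The single array on slide 3 does not account for this, since the median was 1.09 without D28 replicate 3. One differentiation set alone is argued against as well: 2 sets had a within-set median above 0.5, with 0.067, 1.32 and 1.39 in sets 1, 2 and 3. A change with time from day 21 to day 28 stays open and was not tested apart from culture and handling.

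Immediate early and dissociation response genes had medians of 1.97 and 2.12 in D21 and D28 against NP (18 members, 16 above background on all NP arrays). Normalization between arrays is argued against, with a lower D21 median of 1.93 under both other scalings. Handling of the cells in the sort may raise such genes and cannot be told apart from differentiation, because only the later groups were sorted; between these the median was 0.31. A change with differentiation stays open too.

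Probes without a gene name, which no comparison above used, were called 165 times between D21 and NP (60 higher, 105 lower) and 403 times between D28 and NP (92 higher, 311 lower) of 4678 tested, and 0 times between D28 and D21.

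Each pair of groups allows 10 splits of its 6 arrays, too few for a share under 0.05. The real split called 961 genes between D21 and NP and 1890 between D28 and NP (highest other 1 for both), and 1 of 10 splits reached that in each. Between D28 and D21 all 10 splits called the real 0 genes, which decides nothing. The real splits called 23, 25 and 15 gene lists, other splits 9 to 17, 9 to 19 and 6 to 11. In each comparison 1 of 10 reached the real count. Of the other splits of the sorted arrays, those that part all 3 sets, as the real one does, had 280 to 483 genes at an unadjusted p under 0.05, against 313 for the real one. Those that keep both arrays of a set together had 855 to 3081, the most for D21 replicates 1 and 3 with D28 replicate 3. So sets, or in part slides, are a structure beside day. For the 885 genes shared by both days, 3 of 100 splits of the 9 arrays into 3 groups gave as many (highest other 1158), and they were 3 of the 5 splits that kept the NP arrays together, while those mixing them gave at most 0. So the count bears only on NP against the sorted arrays, not on D21 or D28 as groups, and does not exclude chance. For both steps all 100 splits gave the real 0, as any must, so this says nothing about chance.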

How the results depend on the processing

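Numbers here are set against the main values. Only the set block with 2 groups was chosen after the data were seen. Causes were not tested unless stated. The 618 genes higher and 343 lower in D21 than in NP ranged over 182 to 783 and 55 to 400 with 1 array left out, and the 1036 and 854 of D28 over 387 to 1036 and 156 to 1085. The set block with 2 groups, which leaves few degrees of freedom, gave 114 and 18 at D21 and 118 and 63 at D28. Lower genes numbered 206 and 562 without a filter on dim probes, where more genes were tested, 178 and 568 with the set as a block and 183 and 393 with the slide as a block. At D28 682 were higher with the slide as a block, and at D21 216 were lower with only the 2 groups compared. The 885 shared genes ranged over 226 to 903 with 1 array left out, and were 587 without a filter, 587 with only the 2 groups compared, 569 with the slide as a block and 52 with the set block and 2 groups.

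The 63 list shifts numbered 57 to 68 with 1 array left out, 0 with an estimated correlation and 37 by fry. By comparison they were 23, 25 and 15, ranging over 21 to 26, 22 to 26 and 10 to 16 with 1 array left out, 0, 0 and 0 with an estimated correlation, and 2 by fry between D28 and D21. With an estimated correlation, which changes only the p, the medians in D21 against NP were 1.16 for astrocyte markers (adjusted p = 0.306), 1.70 for early glial genes (0.194) and -1.24 for neural progenitor genes (0.194). In D28 against NP they were 1.09 (0.355, by fry 0.0592), 1.64 (0.194), -2.14 (0.194) and, for neuronal genes, -1.38 (0.514, by fry 0.130). Between D28 and D21 neural progenitor genes had -0.34 (0.306, by fry 0.336) and neuronal genes -0.58 (0.355, by fry 0.410). Other calls that fry ended in D21 against NP were those of smooth muscle (0.136), S phase (0.233), mitosis (0.269), BMP and TGF-beta (0.0609), interferon (0.136), cholesterol (0.0803), glutamate and GABA (0.269) and HOX (0.280) genes. In D28 against NP they were smooth muscle (0.288), S phase (0.104), mitosis (0.273), BMP and TGF-beta (0.111), cytokine (0.113) and cholesterol (0.115), and between D28 and D21 endothelial (0.261), S phase (0.663), integrin (0.615), reactive (0.355), cytokine (0.557), interferon (0.158), immediate early (0.497), heat shock (0.505), HOX (0.615), senescence (0.111) and chromatin (0.557). The slide as a block gave -0.27 (0.498) and -0.65 (0.0504) for neural progenitor and neuronal genes between D28 and D21, -0.94 (0.0137) for neuronal genes in D21 against NP and, turned in sign, -0.62 (0.00113) for mitosis genes between D28 and D21. Neuronal genes in D28 against NP had -0.43 (0.567) under the stricter filter.

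With 1 array left out, medians in D21 against NP ran from 0.56 to 1.72 for astrocyte markers, 1.48 to 1.91 for early glial, -1.71 to -1.13 for neural progenitor and -1.83 to -0.14 for neuronal genes. In D28 against NP the ranges were 0.61 to 1.53, 1.49 to 1.97, -2.36 to -1.58 and -2.04 to -0.69. Between D28 and D21 they were -0.48 to 0.44, -0.23 to 0.14, -0.90 to -0.15 and -1.19 to -0.089, and the called medians that changed sign there were those of S phase (-0.90 to 0.085), integrin (-0.046 to 0.39), cytokine (-0.11 to 0.99) and immediate early genes (-0.086 to 0.58). Of the lists not called there, all changed sign but neural crest and pluripotency genes, among them mesenchymal (-0.77 to 0.42), mitosis (-0.67 to 0.54) and smooth muscle genes (-1.1 to 0.17).

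Of 96 named genes called at D21, 25 kept the call in every processing alternative that tested them and 33 without each array, and of 123 at D28 24 and 47; 0 changed sign. The set block with 2 groups ended most calls (66 and 96) and, of the arrays, NP replicate 3 (59 and 73). The set as a block ended 25 and 22, the slide as a block 20 and 39, no filter 22 and 18, only the 2 groups compared 21 and 15, each array's median 13 and 6 and normexp 9 and 12. Neither block for the set ended a list call, and with 2 groups it added 3 between D28 and D21 and 2 in D21 against NP. Fry added 2 in D21 and 1 in D28 against NP. Among called genes 80 and 131 had a dim group not above background on all its arrays, so their size is limited by background.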

Other observations

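The median of HOX genes, relative to each gene's mean over 9 arrays, was -2.95 in NP replicate 1, 1.37 in replicate 2 and -0.94 in replicate 3. CD44 on the NP arrays was 2.12, -0.35 and -1.23 relative to the 75th percentile, against a mean of 4.83 in D21 and 5.82 in D28.

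Among the sorted arrays, mitosis genes had medians of -1.81 in D21 replicate 2 and -1.49 in D28 replicate 1, against 0.51 in D21 replicate 1 and 0.75 in D28 replicate 3. Neuronal genes had 1.64 in D21 replicate 2, against -1.04 and -0.64 in the other D21 arrays. Cytokine and chemokine genes had 1.90 in D28 replicate 1, against -0.32 and 0.30 in the other D28 arrays.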
